A study of Mus musculus with 6 samples.

How the data were processed

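Total RNA from V720 cells treated for 24 h with vehicle or 1 µM PD0332991 was purified, biotin-labelled by the standard Affymetrix procedure and hybridized to expression arrays, per the labels' protocols. The samples fell into 2 groups of 3 by their titles and treatment labels. The values analysed were the authors' deposited table, which holds 1 linear probe-set intensity per array for 45101 probe sets. The scanner files were not used here, and the summarisation method and its scaling target were not given in the sources used here. The values were all positive, and the column medians and means were nearly but not exactly equal (2% trimmed means of 409 ± 4.66 and 402 ± 1.87, SD, n = 3, for vehicle and PD0332991), so that the arrays were at a like level and no further normalization was applied. If the arrays had been scaled to a common level, a change in total RNA per cell would not be seen. Every column of values was mapped to a sample by its label.

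The 64 control probe sets were left out. Of the other 45037, the platform annotation gave exactly 1 gene symbol to 34945, several to 932 and none to 9160, and annotation symbols can be old. The 34945 probe sets named 18194 genes, of which 18032 matched a mouse RefSeq gene table (assembly GRCm38.p6) by gene number, and no symbol needed an update. That table was used for names, chromosomes and the order of genes, and no coordinates are given because the array annotation names no build. A gene with several probe sets, as 9009 had, was represented by the one with the highest mean log2 value over the 6 arrays. Probe sets with several or no gene symbols were tested apart and are described only as counts.

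Intensities were transformed to log2(intensity + 16), and a fold change is on that scale, which understates the change of dim genes. PD0332991 and vehicle arrays were compared gene by gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 18194 genes and a threshold of 0.05. The design had no replicate block and no filter on dim genes. Gene lists were tested with camera of limma with a preset correlation of 0.01, adjusted over the 25 lists, and beside it with camera with an estimated correlation and with fry. The last of these tests whether a list's genes move, on balance, one way and does not compare them with other genes. Tables were joined in Python 3.11.15 with pandas 2.3.3, and the plots were drawn with matplotlib 3.10.9.

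The test, the named-gene rule, the 25 gene lists and most alternatives were fixed before the data were examined. The lists covered the cyclin-CDK-RB axis, G1/S and DNA replication, G2/M and mitosis, nucleotide synthesis, homologous recombination and Fanconi anaemia, replication-dependent histones, p53 targets, interferon-stimulated genes, antigen presentation, senescence-associated secretory genes, MYC targets and ribosome biogenesis, cholesterol synthesis, fatty acid and triglyceride synthesis, glycolysis, oxidative phosphorylation, lysosome and autophagy, the unfolded protein response and immediate early genes. They also covered luminal, basal and epithelial-mesenchymal genes and markers of fibroblasts, endothelium, leukocytes and adipocytes. The arrays held 650 list entries, and 38 entries were not analysed here. The genes named were, first, the 10 with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap and whose brighter group was above the median of all genes, passing over predicted genes and unnamed clones. Added to these were 9 genes of the drug targets and their partners in every case, and, for each list, up to 4 members: those with the smallest p, at most 2 that rose and 2 that fell, or the 2 with the smallest p where none was called.

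The procedure was tested on simulated data for 18194 genes in 3 against 3 arrays, with 200 genes changed. It recovered 18% of changes of 0.25 on the log2 scale, 64% of changes of 0.5, 86% of changes of 1 and 96% of changes of 2, and 6 of its 138 calls were unchanged genes. The simulated noise was independent between genes, and far fewer genes changed than the 3820 called in the data. These rates therefore need not hold for the real comparison. The alternatives were a replicate block, quantile normalization, centring on the array median, pseudocounts of 1 and 64, a filter on dim genes, the mean of a gene's probe sets, each probe set on its own, eBayes with trend and robust settings, array weights, each array left out in turn, an adjusted p threshold of 0.01, a 2-fold minimum, and the other list tests. Centring on the 9 hybridization spike-in probe sets, with all arrays or without vehicle replicate 1, and leaving out probe sets of the types whose probes can match several transcripts, were added after the data were seen. The spike-ins averaged 9.91 ± 0.149 on the vehicle and 10.03 ± 0.028 on the PD0332991 arrays (log2, SD, n = 3). With 10 possible splits of 6 arrays into 3 and 3, the share of splits with a result as large as the real one cannot fall below 10%.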

Results

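Gene expression was measured in V720 cells, a mouse breast cancer line that the labels place in the mammary epithelium. The cells received either vehicle or 1 µM PD0332991 for 24 h. PD0332991 (palbociclib) is a small-molecule inhibitor of the kinases CDK4 and CDK6, which pair with D-type cyclins, phosphorylate the retinoblastoma protein and so release E2F transcription factors at entry into S phase. Each group held 3 samples by its labels, each hybridized to its own Affymetrix mouse expression array, 6 arrays in all. The median probe-set intensity was 71.8 ± 0.79 (SD, n = 3) on the vehicle arrays and 70.1 ± 0.84 (SD, n = 3) on the PD0332991 arrays. Pairs of arrays from the same group had correlations across genes of 0.9969 to 0.9973, and pairs from different groups 0.9919 to 0.9927. No pair of arrays was a duplicate, the SD of log2 differences between arrays of the same group being 0.183 to 0.197. The first principal component held 58.8% of the variance and separated the groups. The number of arrays limits the precision, and because nothing in the labels says that the 3 samples of a group came from separate experiments, the p-values measure only the spread between these samples, which may be technical.

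The comparison of PD0332991 with vehicle asked which transcripts differ after 24 h of CDK4 and CDK6 inhibition. Genes of DNA replication and of mitosis fell together: all 49 measured genes of the G1/S and DNA replication list and 63 of 64 of the G2/M and mitosis list were lower, with median log2 fold changes of -1.0 and -1.64. Interferon-stimulated genes rose, 22 of 30 being higher with a median log2 fold change of 0.70, and 5 of 14 leukocyte markers rose on the same arrays. With an estimated correlation within lists, camera called neither the G2/M nor the interferon list (adjusted p = 0.108 for both). The fry test, which does not compare a list with other genes, called both (adjusted p = 4.05e-05 and 0.0002). Cyclin D2 (Ccnd2) rose 2.81-fold and the CDK inhibitor p21 (Cdkn1a) 1.74-fold, while the proliferation marker Mki67 fell from an intensity of 4196 ± 112 (SD, n = 3) to 1037 ± 72.4 (SD, n = 3). Genes of the p53 and senescence-associated secretory lists rose by smaller amounts, in 18 of 27 and 17 of 35 cases. When arrays were centred on the hybridization spike-ins, 2 and 10 rose (7 and 12 when vehicle replicate 1 was also left out).

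Of 18194 genes tested with limma, 3820 were called at the adjusted p threshold of 0.05, of which 1785 were higher and 2035 lower with PD0332991. There were 2538 calls without vehicle replicate 1, 2497 without vehicle replicate 3 and 2522 without PD0332991 replicate 2, with 1096, 1171 and 1129 higher, and 1189 were higher without PD0332991 replicate 3. The large changes were mostly decreases, since 209 of the lower and 29 of the higher genes changed at least 2-fold. The groups did not overlap in any of the 3820 called genes, and did not overlap in 38.9% of all genes, where chance gives 10%. Higher genes made up 46.7% of the calls. That share was 56.9%, from 2137 higher and 1617 lower genes, when each array was centred on its median. It was 14.0%, from 240 higher and 1475 lower genes, when arrays were centred on the hybridization spike-ins, a setting chosen after the data were seen that moves the median of all genes to -0.12 on the log2 scale. Most of that shift comes from vehicle replicate 1, with a spike-in mean of 9.74 (log2) against 9.94 to 10.05 on the other 5 arrays. Without that array, spike-in centring gave 412 higher and 1159 lower genes (26.2% higher) and a median of -0.04. Spike-in-centred values below include it unless stated. Because spike-in centring lowers every log2 fold change alike, a fall whose call is lost there has become larger, not smaller.

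**Figure D1:**
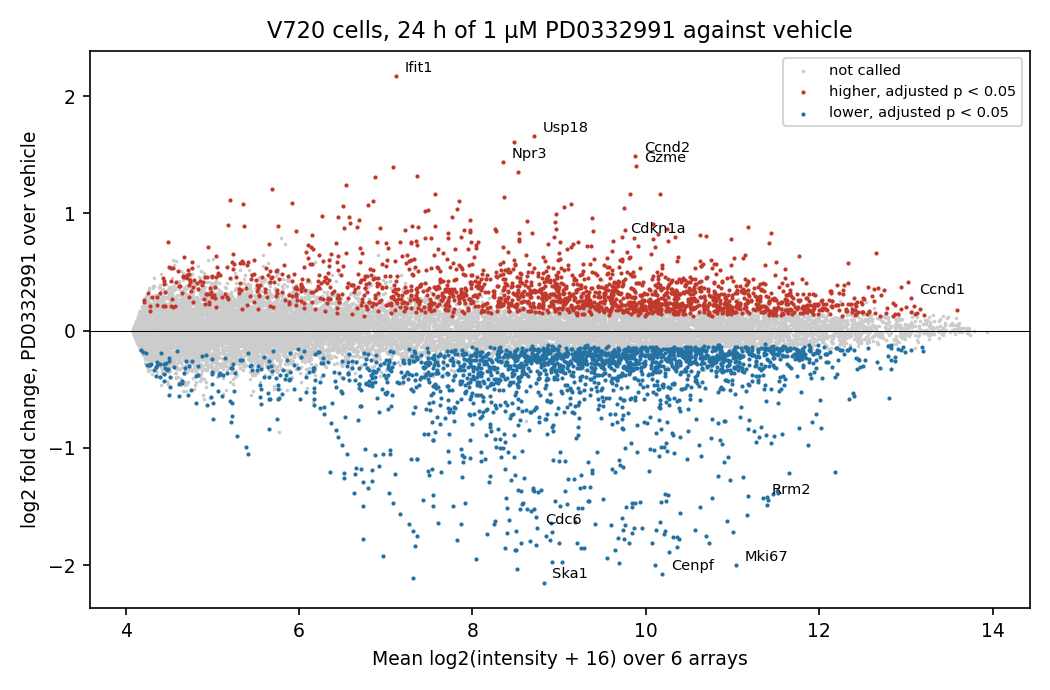
Mean log2(intensity + 16) over the 6 arrays (horizontal axis) against the log2 fold change of PD0332991 over vehicle (vertical axis), with 1 point per gene. Red points are the 1785 genes called higher, blue points the 2035 called lower and grey points the rest. The lower genes reach -2.15 (Ska1) and the higher genes 2.17 (Ifit1).

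In the 10 largest falls, every gene was at least 3.86-fold lower, and several of them act in mitosis. Ska1, part of the complex that couples kinetochores to microtubules (chromosome 18), fell from an intensity of 940.8 ± 37.5 to 199.8 ± 12 (SD, n = 3 each), a 4.44-fold lower level (log2 fold change -2.15, SE 0.06, adjusted p = 4.50e-05). Lockd, a long noncoding RNA, was 4.33-fold lower, Cenpf, a kinetochore protein, 4.22-fold, and Cdkn3, a phosphatase of CDKs, 4.09-fold. Aspm, a spindle pole protein, and Mki67 were each 4.01-fold lower. The mitotic kinesin gene Kif20a was 3.95-fold lower, Esco2, which acetylates cohesin in S phase, 3.94-fold, and the kinase gene Melk 3.92-fold. E2f7, a repressor of E2F target genes, was 3.86-fold lower. The adjusted p of these 10 genes lay between 4.50e-05 and 6.46e-05.

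Among the 10 largest rises were 3 interferon-stimulated genes. Ifit1, which binds viral RNA (chromosome 19), rose from an intensity of 49.8 ± 6.66 to 280.7 ± 34.2 (SD, n = 3 each), a 4.51-fold higher level (log2 fold change 2.17, SE 0.11, adjusted p = 0.000127). Usp18, which removes the ubiquitin-like modifier induced by interferon and dampens interferon signalling, rose from 220.1 ± 1.87 to 732.8 ± 78.6 (SD, n = 3 each). Oasl2, of the oligoadenylate synthetase family, rose 2.63-fold. Ccnd2 rose from 547.6 ± 46.5 to 1566 ± 83.8 (SD, n = 3 each), and all 7 of its probe sets were called higher. Npr3, the natriuretic peptide clearance receptor, rose 2.71-fold, Sftpd, surfactant protein D, 2.55-fold, Sparc, a matrix glycoprotein, 2.49-fold, and Tslp, an epithelial cytokine, 2.48-fold. The granzyme gene Gzme rose 2.64-fold, on a single probe set of the type whose probes can match other transcripts. H3f3b, which encodes histone H3.3, rose 3.05-fold on a single probe set with intensities of 194.3 ± 66.3 and 612.5 ± 104 (SD, n = 3 each, SE of the log2 fold change 0.24, adjusted p = 0.00763), the widest error of the 10, and it has near-identical copies in the genome.

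The genes of the drug targets and their partners changed in both directions. Cdk6 rose from an intensity of 1016 ± 27.1 to 1310 ± 33.4 (SD, n = 3 each, log2 fold change 0.36, SE 0.04, adjusted p = 0.00255). Cdk4 fell from 3349 ± 78.2 to 2976 ± 77.1 (SD, n = 3 each, log2 fold change -0.17, SE 0.04, adjusted p = 0.0305), a call that was lost when any 1 array was left out. Cyclin D1 (Ccnd1) rose 1.21-fold at a high intensity of 7742 ± 180 with vehicle (SD, n = 3), and its other 2 probe sets gave log2 fold changes of 0.44 and 0.58. The cyclin E genes, which drive S phase entry and are E2F targets, both fell, Ccne1 1.58-fold and Ccne2 2.60-fold. Rb1, which encodes the retinoblastoma protein, fell 1.27-fold (log2 fold change -0.34, SE 0.06, adjusted p = 0.0131). E2f1 had intensities of 389.8 ± 18 and 387.4 ± 37.7 (SD, n = 3 each) on its brightest probe set (log2 fold change -0.01, adjusted p = 0.938), while another, dimmer probe set had a log2 fold change of -0.72 (SE 0.06, adjusted p = 0.00118). Cdkn2a had a low signal in both groups, 7.91 ± 2.79 and 9.77 ± 3.31 (SD, n = 3 each, adjusted p = 0.617).

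Over the cyclin-CDK-RB list, 4 of 28 measured genes rose and 12 fell, and the counts adjusted over the list alone were also 4 and 12. Besides Ccnd2 and Cdkn1a (627 ± 28.1 to 1104 ± 72.4, SD, n = 3 each), Ccnd1 and Cdk6 were the genes that rose, and after spike-in centring the counts were 2 and 11. The falls included E2f7 and Cdkn2d, an inhibitor of CDK4 and CDK6 that was 2.79-fold lower. The list shifted down in the camera test (adjusted p = 0.000742), with adjusted p = 0.112 with an estimated correlation.

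**Figure D2:**
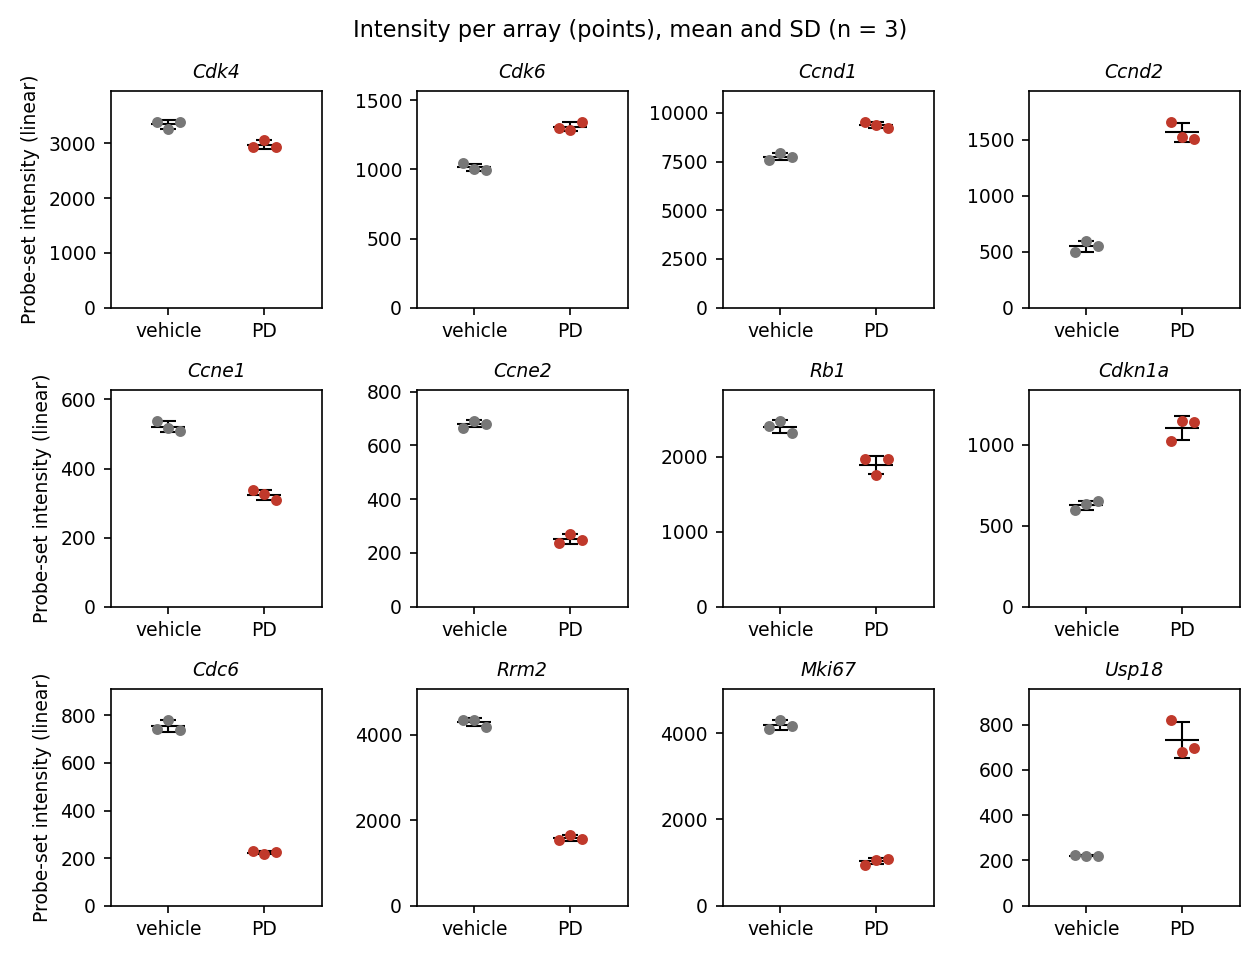
Linear probe-set intensity (vertical axis) of 12 genes on each of the 3 vehicle arrays (grey) and 3 PD0332991 arrays (red), with the mean as a bar and the SD as its error. The 3 arrays of one group lie apart from the 3 of the other for each gene drawn, with Mki67 at 4196 ± 112 against 1037 ± 72.4 and Ccnd2 at 547.6 ± 46.5 against 1566 ± 83.8.

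The genes of G1/S and DNA replication fell without exception, 49 of 49 over all genes and 49 adjusted over the list alone, with log2 fold changes from -1.76 to -0.35. Cdc6, which loads the replicative helicase, fell from an intensity of 754.5 ± 24.5 to 223.4 ± 7.45 (SD, n = 3 each), and Clspn, an adaptor of the replication checkpoint, was 2.87-fold lower. Camera gave adjusted p = 3.18e-46, and adjusted p = 0.0269 with an estimated correlation. In the G2/M and mitosis list 63 of 64 genes fell, and 63 adjusted over the list alone. Mad2l1, of the spindle assembly checkpoint, was 2.69-fold lower and Cdca3, which takes part in mitotic entry, 3.43-fold. The dimmer probe sets of Cdca3 had log2 fold changes of 0.05 and -0.01. The remaining member, the kinesin gene Kif15, chosen for naming after its value was seen, had a log2 fold change of -0.20. For this list camera returned adjusted p = 6.38e-57, and adjusted p = 0.108 with an estimated correlation, which was 0.67.

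On the log2 scale the mean of the G2/M list, taken relative to that of the G1/S list on each array, changed by -0.55 from vehicle to PD0332991, with an SD between arrays of 0.011 and 0.093 (n = 3 each). With 3 arrays against 3, the smallest p that an exact two-sided permutation test allows is 0.1.

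Genes that supply and repair DNA followed the same direction in part. Of 28 nucleotide synthesis genes 19 fell and none rose; adjusted over the list alone, 20 fell and 1 rose. Both subunits of ribonucleotide reductase, which makes deoxyribonucleotides, fell: Rrm2 from an intensity of 4292 ± 90.1 to 1583 ± 68.1 (SD, n = 3 each) and Rrm1 1.87-fold. Camera gave adjusted p = 1.47e-09, and 0.0474 with an estimated correlation. Of 28 homologous recombination and Fanconi anaemia genes 22 fell and none rose, and adjusted over the list alone 24 fell. Exo1, a nuclease that resects DNA ends, was 2.87-fold lower and Brca2, which loads the recombinase onto single-stranded DNA, 2.04-fold (camera adjusted p = 3.30e-18, and 0.0216 with an estimated correlation). Replication-dependent histone genes moved the other way, with 6 of 11 higher and 1 lower (7 and 1 adjusted over the list alone, 3 and 0 after spike-in centring). H2ac19 rose from an intensity of 752.8 ± 39.2 to 1709 ± 39.9 (SD, n = 3 each) and H3c7 2.16-fold, while H2bc21 fell 1.19-fold. The shift of the histone list had a camera adjusted p = 0.000265, and adjusted p = 0.112 with an estimated correlation. These genes have near-identical copies, so that a probe set cannot always be assigned to 1 of them. A change in the polyadenylated share of their transcripts, which the labelling may depend on, was not tested.

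Interferon-stimulated genes rose in 22 of 30 measured cases, or 24 adjusted over the list alone, and none fell. The list median of 0.70 kept its sign under every scaling tried, from 0.57 after spike-in centring to 0.74 after quantile normalization. Its camera test gave adjusted p = 5.89e-17, and adjusted p = 0.108 with an estimated correlation. In the antigen presentation list 7 of 16 genes rose (10 adjusted over the list alone) and none fell. But after spike-in centring 1 rose and the list median was 0.06 (1 and 0.14 when vehicle replicate 1 was also left out). Leaving out that array without spike-in centring gave 5 higher and a median of 0.18. The 7 genes included Psmb8, a subunit of the immunoproteasome, which was 1.56-fold higher, and Psmb10, another such subunit, which was 1.33-fold higher (camera adjusted p = 1.96e-05 for the list, and adjusted p = 0.169 with an estimated correlation). The call of Psmb8 ended with the mean of its probe sets, the dimmer of which had a log2 fold change of 0.06. On the same arrays 5 of 14 leukocyte markers were higher and 1 lower, with a median log2 fold change of 0.12 (none higher and -0.01 after spike-in centring). Leaving out vehicle replicates 1 to 3 in turn gave 2, 3 and 2 higher markers, and PD0332991 replicates 1 to 3 gave 3, 1 and 2.

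Of 27 p53 target genes 18 rose and none fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.25. After spike-in centring 2 of the 27 rose and the median was 0.12 (7 and 0.18 when vehicle replicate 1 was also left out). Leaving out that array without spike-in centring gave 13 higher and a median of 0.23. Ccng1, a cyclin induced by p53, rose from an intensity of 3192 ± 19.0 to 4225 ± 40.6 (SD, n = 3 each), and Cdkn1a is also a member. The list was called by camera at adjusted p = 4.4e-09, and at 0.0474 with an estimated correlation. Senescence-associated secretory genes rose in 17 of 35 cases and fell in 1 (19 and 1 adjusted over the list alone, 10 and 1 after spike-in centring). Ccn2, a matricellular growth factor, rose from 5107 ± 59.3 to 8075 ± 182 (SD, n = 3 each) and the chemokine gene Cxcl1 rose 1.73-fold, while Tgfb2, of the TGF-beta family, was 1.17-fold lower (adjusted p = 0.0460). The shift upward had a camera adjusted p = 1.29e-07, and 0.0474 with an estimated correlation. Immediate early genes rose in 11 of 24 cases and fell in 1 (13 and 2 adjusted over the list alone), but after spike-in centring 1 rose and 1 fell (3 and 0 when vehicle replicate 1 was also left out). The count that rose was 7 without vehicle replicate 1, 7 without PD0332991 replicate 1 and 6 without PD0332991 replicate 2. The stress-response gene Ier3 was 1.29-fold higher, the transcription factor genes Myc 1.33-fold higher and Egr3 1.25-fold lower (camera adjusted p = 9.19e-05, and 0.0474 with an estimated correlation).

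Growth and metabolic lists moved by small amounts. In the MYC target and ribosome biogenesis list, Myc itself rose and 9 of 39 genes fell (2 and 10 adjusted over the list alone). After spike-in centring 3 were called lower, although the list median moved from -0.09 to -0.22. Among the 9 genes were Dkc1, a pseudouridine synthase (1.24-fold lower), and Nop58, a nucleolar protein (1.21-fold lower). Camera gave adjusted p = 0.00228, and adjusted p = 0.410 with an estimated correlation. Lysosome and autophagy genes rose in 16 of 33 cases and none fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.16. After spike-in centring 1 rose, and 10 rose without vehicle replicate 1, vehicle replicate 3 or any 1 of PD0332991 replicates 1 to 3. Gusb, a lysosomal glucuronidase, was 1.58-fold higher and the autophagy gene Wipi1 1.24-fold (camera adjusted p = 4.48e-08 for the list, and adjusted p = 0.183 with an estimated correlation). Another, dimmer probe set of Gusb had a log2 fold change of -0.20 (limma adjusted p = 0.0771). Unfolded protein response genes rose in 10 of 28 cases and fell in 1 (18 and 2 adjusted over the list alone), but none rose after spike-in centring (2 when vehicle replicate 1 was also left out). Their count was 5 without vehicle replicate 1, 4 without vehicle replicate 3 and 6, 4 and 6 without PD0332991 replicates 1 to 3 in turn. The chaperone gene Dnajb9 was 1.38-fold higher, Asns, asparagine synthetase, 1.26-fold higher and Psat1, of serine synthesis, 1.11-fold lower (camera adjusted p = 1.60e-05, and adjusted p = 0.165 with an estimated correlation).

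Cholesterol synthesis genes rose in 6 of 20 cases and fell in 1 (6 and 2 adjusted over the list alone). Their median log2 fold change was 0.09 (0.05 without vehicle replicate 1 and 0.11 without vehicle replicate 2). After spike-in centring it became -0.04, with 1 gene higher (0.0055 and 2 when vehicle replicate 1 was also left out). The sterol reductase gene Tm7sf2 rose from an intensity of 584.8 ± 22 to 1223 ± 69.7 (SD, n = 3 each), Nsdhl, a sterol dehydrogenase, rose 1.27-fold, and the sterol carrier gene Stard4 fell 1.17-fold. As a list they had a camera adjusted p = 0.00843, and adjusted p = 0.392 with an estimated correlation. Of 37 oxidative phosphorylation genes 2 fell, Ndufb8 of complex I (1.14-fold) and Atp5b of the ATP synthase (1.10-fold). None was called lower or higher adjusted over the list alone. None was called lower when any 1 array was left out, or after spike-in centring, although the list median was then -0.17. With trend and robust settings 10 were called lower. Without spike-in centring the list median was -0.04 (camera adjusted p = 0.0251, and adjusted p = 0.418 with an estimated correlation), and the call of the list ended after median centring (adjusted p = 0.15). Fatty acid and triglyceride synthesis genes were not called as a list (camera adjusted p = 0.194), with a median log2 fold change of 0.07, and of -0.06 after spike-in centring. In that list 2 of 21 genes rose, Lpin1 (1.26-fold) and Acss2 (1.44-fold), and 2 fell, Elovl6 (1.18-fold) and Acsl3 (1.10-fold), with the same counts adjusted over the list alone. The calls of Lpin1, Elovl6 and Acsl3 ended after spike-in centring, with or without vehicle replicate 1, leaving 1 higher and none lower. With trend and robust settings 7 rose, while 1 rose without vehicle replicate 1, vehicle replicate 3, PD0332991 replicate 1 or PD0332991 replicate 2. The genes that fell were 0, 0 and 1 without vehicle replicates 1 to 3 and 1, 0 and 0 without PD0332991 replicates 1 to 3. Nor were the glycolysis genes called as a list (camera adjusted p = 0.0733, median 0.05, and -0.08 after spike-in centring). There 2 of 17 rose, Pfkfb3, which makes an activator of glycolysis (1.42-fold), and the hexokinase gene Hk2 (1.33-fold), none of them after spike-in centring (2 genes when vehicle replicate 1 was also left out) and 5 genes with trend and robust settings, with the same counts adjusted over the list alone.

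The luminal and basal lists were not called. Of 30 luminal and milk genes 4 rose and 6 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.885). Without vehicle replicate 1, vehicle replicate 2, PD0332991 replicate 2 or PD0332991 replicate 3 the luminal genes that rose were 2, 2, 0 and 2, and without vehicle replicate 3 or PD0332991 replicate 1 those that fell were 3 and 3. The tight junction gene Cldn4 (1.54-fold) and the keratin gene Krt7, at an intensity of 7642 ± 112 with vehicle and 8789 ± 217 with PD0332991 (SD, n = 3 each), were higher, while the transcription factor genes Elf5 and Ehf were 1.29-fold and 1.26-fold lower. After spike-in centring 1 luminal gene rose and 7 fell (1 and 4 when vehicle replicate 1 was also left out). The luminal median was 0.03 (-0.09 after spike-in centring), its mean -0.0053, and fry put its direction below 0 (adjusted p = 0.587). Of 19 basal and myoepithelial genes 2 rose, the laminin gene Lamb3 (1.31-fold) and the integrin gene Itgb4 (1.18-fold), and Vim, vimentin, fell 1.32-fold, with the same counts adjusted over the list alone (camera adjusted p = 0.194, median 0.08, and -0.05 after spike-in centring). The calls of Lamb3 and Itgb4 ended after spike-in centring, with or without vehicle replicate 1, leaving none higher and 1 lower, and that of Itgb4 also without PD0332991 replicate 2, leaving 1 higher.

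The epithelial-mesenchymal transition list was called upward, with 5 of 17 genes higher and 1 lower (6 and 1 adjusted over the list alone, 2 and 1 after spike-in centring). The matrix genes Tnc (1.58-fold) and Sparc were higher, and Vim, a mesenchymal filament protein, was the member that fell. Camera gave adjusted p = 0.0251, and adjusted p = 0.141 with an estimated correlation.

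Markers of cells other than mammary epithelium were mostly dim. Among 16 fibroblast markers none rose and Pdgfra, a growth factor receptor, fell 1.43-fold (also adjusted over the list alone, camera adjusted p = 0.885). The dimmer probe sets of Pdgfra had log2 fold changes of 0.04 and -0.11. Its call ended with the mean of probe sets, where 1 fibroblast marker was higher and none lower. The fibroblast median was 0.02 (-0.11 after spike-in centring), with a mean of -0.02 and a direction below 0 in camera. Among 12 endothelial markers Flt1, a receptor for vascular endothelial growth factor, rose 1.20-fold and Emcn had an intensity of 13.2 ± 0.74 with vehicle and fell to 5.71 ± 0.29 (SD, n = 3 each), with the same counts adjusted over the list alone (camera adjusted p = 0.475, median 0.08, -0.05 after spike-in centring, and direction below 0 in fry). The call of Flt1 ended after spike-in centring, with or without vehicle replicate 1, and when any 1 array except PD0332991 replicate 2 was left out. No endothelial marker was then higher after spike-in centring or without vehicle replicate 1, 2 or 3 or PD0332991 replicate 3. Among 14 leukocyte markers 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0921). Cd68, a lysosomal protein of macrophages, rose from 230.1 ± 15.2 to 307.7 ± 14.7, Ptprc, the common leukocyte antigen, from 11.6 ± 1.67 to 18.2 ± 1.02, and Laptm5, a lysosomal protein of leukocytes, fell from 114.0 ± 15.4 to 83.7 ± 6.23 (SD, n = 3 each). None of 7 adipocyte markers was called, over all genes or adjusted over the list alone (camera adjusted p = 0.946). Adipoq, which encodes adiponectin, had log2 fold change 0.17 (adjusted p = 0.297) and Cidec, a lipid droplet gene, 0.27 (adjusted p = 0.429). Their list median was 0.0046, with a direction below 0 in fry and -0.12 after spike-in centring. The adipocyte median was 0.04 without vehicle replicate 1 and -0.08 without vehicle replicate 2.

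**Figure D3:**
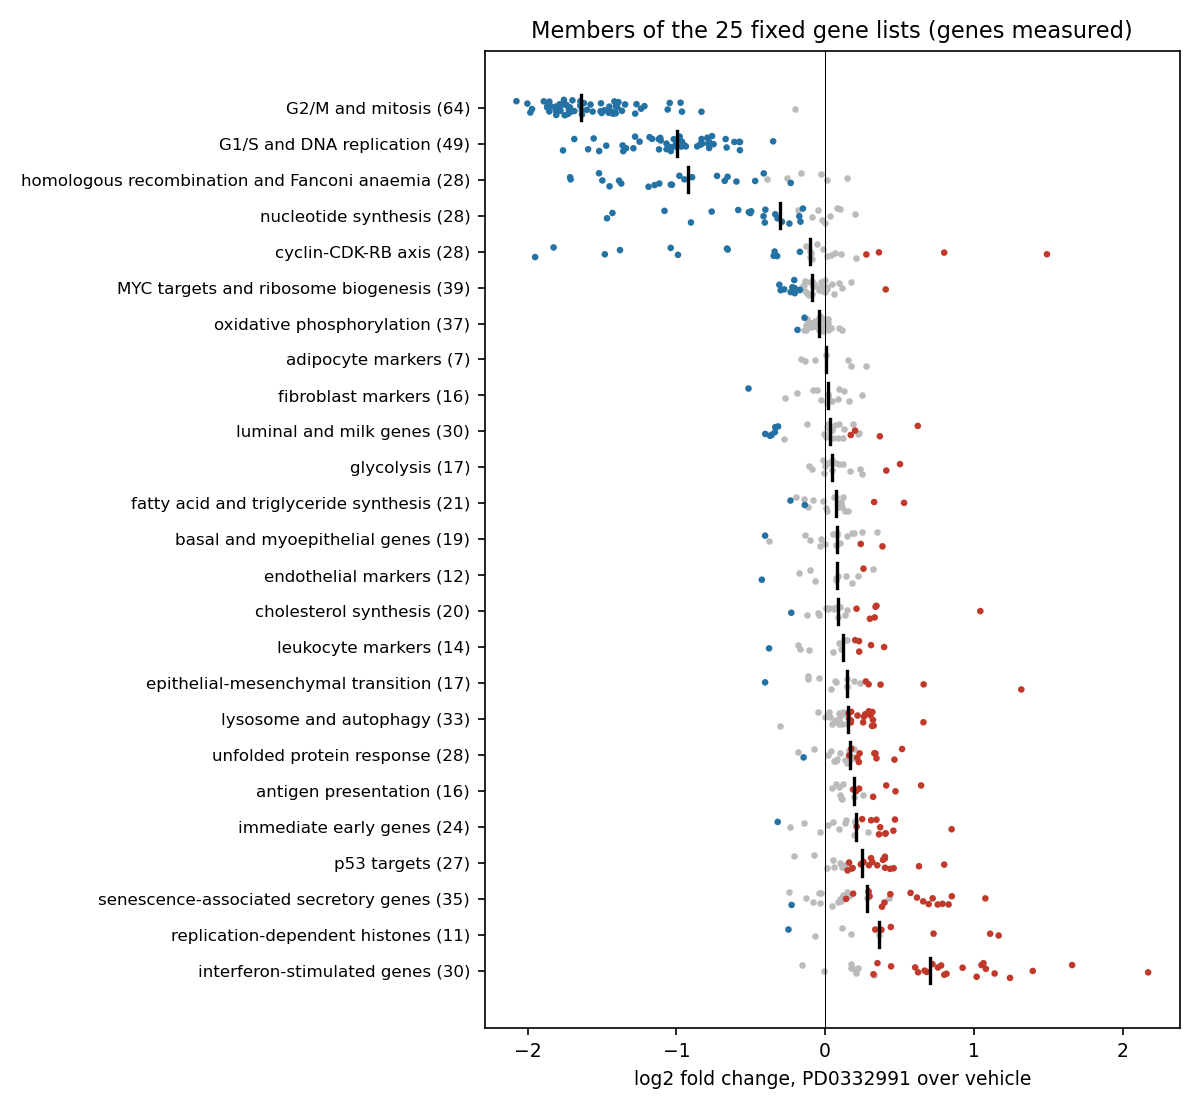
Log2 fold change of PD0332991 over vehicle (horizontal axis) for every measured member of the 25 gene lists, 1 point per gene, with the number of genes measured beside each list. Red and blue points are genes called higher and lower, grey points were not called, and the black bar is the list median, from -1.64 for G2/M and mitosis to 0.70 for interferon-stimulated genes. After spike-in centring, 9 lists have medians of the opposite sign: cholesterol synthesis, fatty acid and triglyceride synthesis, glycolysis, and the luminal, basal, fibroblast, endothelial, leukocyte and adipocyte lists. When vehicle replicate 1 is also left out, 4 do: glycolysis and the luminal, fibroblast and adipocyte lists.

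Over the 25 lists, camera with a preset correlation called 17, 10 up and 7 down, and 6 were also called with an estimated correlation. Those 6 were the lists of G1/S and DNA replication, nucleotide synthesis, homologous recombination and Fanconi anaemia, p53 targets, senescence-associated secretory genes and immediate early genes. Outside the lists stood 3493 of the 3820 called genes. Where a gene had several probe sets and the one used was called, 1083 of 2338 genes had another probe set called in the same direction and 35 had one called in the opposite direction. Leaving out 1 array at a time ended the call of 16 named genes: Cdk4, Acsl3, Atp5b, Ndufb8 and Psat1 with each of the 6 arrays, and Acss2, Cldn4, Egr3, Elovl6, Flt1, Itgb4, Krt7, Laptm5, Ptprc, Stard4 and Tgfb2 with some of them. After spike-in centring 28 named genes were no longer called, among them Cdk4, Cdk6, Ccnd1, Ccng1, Myc, Psmb10, Wipi1, Dnajb9, Ier3 and Cd68.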

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

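Of the tests in this part, the count of leukocyte markers and both tests on the histone genes were chosen only after the result was seen. The genes Adgre1, Fcer1g, Tyrobp, Cd14, Csf1r, Lyz2, Ifng and Ifna5 were likewise chosen for naming after their values were seen.

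Probe sets without a single gene name, which the comparison of genes did not use, also differed between the groups. Of 10092 such probe sets, 112 were called higher and 240 lower with PD0332991 by limma, adjusted over these probe sets, and 11 of the higher and 25 of the lower changed at least 2-fold.

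The rise of interferon-stimulated genes is the first pattern weighed. Array scaling does not account for it: the lowest list median over the 3 other scalings was 0.57, after spike-in centring, against 0.70 as reported. RNA from leukocytes in the treated cultures stays open, because the 14 leukocyte markers were mixed. Limma called 5 higher (Cd68, Adgre1, Fcer1g, Ptprc and Tyrobp, with adjusted p from 0.00874 to 0.0491) and Laptm5 lower. None was called higher after spike-in centring. Ptprc and Tyrobp were near the pseudocount of 16, with mean intensities of 11.6 and 12.8 with vehicle and 18.2 and 17.8 with PD0332991. Among markers not called, Cd14, Csf1r and Lyz2 had log2 fold changes of 0.13, 0.05 and -0.11 (limma adjusted p = 0.0943, 0.727 and 0.511). The list was called by fry (adjusted p = 0.0023) and with camera on the mean of probe sets (0.0394) or without shared probes (0.0348). It was not called by camera as reported (0.0921). A rise of interferon transcripts remains open, since limma called 0 of 10 interferon genes higher (1 at an unadjusted p under 0.05, Ifng, at a log2 fold change of 0.40 and adjusted p = 0.0883) and Ifna5 lower (log2 fold change -0.56, adjusted p = 0.0322), and most of these genes were too dim to decide it. A response to the drug, which the design names, is a hypothesis that may account for the rise and was not tested apart from the group difference itself.

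The rise of replication-dependent histone genes, opposite to the fall of the replication list, is the second. Near-identical copies sharing probe sets do not account for the whole of it, since 12 probe sets of these genes without the suffix for shared probes had a median log2 fold change of 0.35. Array scaling left a list median of at least 0.24 over the 3 other scalings, although after spike-in centring 3 of the 11 genes were called higher. Probe sets without that suffix can still match close copies in part, and a change in the polyadenylated share of histone transcripts, which the labelling may depend on, was not tested.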

How the results depend on the processing

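Spike-in centring, with and without vehicle replicate 1, and leaving out probe sets with shared probes were chosen only after the data were seen, and the other settings were planned. The real split of the 6 arrays gave 3820 calls and the highest of the other splits 0 (696 at an unadjusted p under 0.05, against 6062), so that 1 of 10 splits gave as many, too few splits for a share under 0.05. The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.0075, -0.051 and 0.049, and 2 of 6 arrays correlated best with their own number. With the replicate number as a block, which costs residual degrees of freedom, 2046 genes were called, 894 higher and 1152 lower, of which 1973 were among the 3820. Leaving out each array in turn gave 2497 to 2683 calls, 1096 to 1252 higher and 1326 to 1494 lower, with fewer arrays in each fit. At an adjusted p under 0.01 there were 1703 calls, 708 higher and 995 lower, and with a change of at least 2-fold 238, 29 higher and 209 lower (12.2% higher). Testing each probe set on its own called 6391 probe sets, 2701 higher and 3690 lower. The share of higher calls was 56.9% after median centring and 56.3% after quantile normalization. Spike-in centring, which shifts each array by 1 constant, called 1715 genes, 240 higher (14.0%, a shift of -32.7 percentage points) and 1475 lower. The spike-ins differed between the groups by 0.127 on the log2 scale, within their SD of 0.149 between the vehicle arrays, and by 0.046 without vehicle replicate 1, where spike-in centring called 1571 genes, 412 higher (26.2%) and 1159 lower, so that the split between higher and lower calls cannot be told apart from array scaling. The other settings kept the counts within 1.5 times. With an estimated correlation 6 lists were called. The adjusted p of the others that camera had called was 0.112 for the cyclin-CDK-RB axis and for replication-dependent histones, 0.108 for G2/M and mitosis and for interferon-stimulated genes, 0.169 for antigen presentation, 0.410 for MYC targets, 0.392 for cholesterol synthesis, 0.418 for oxidative phosphorylation, 0.183 for lysosome and autophagy, 0.165 for the unfolded protein response and 0.141 for epithelial-mesenchymal transition. All of these lists were called by fry (adjusted p from 4.05e-05 to 0.0173), which does not compare a list with other genes. The estimated correlation was 0.67 for G2/M and mitosis, 0.30 for interferon-stimulated genes and 0.27 for lysosome and autophagy, against the preset 0.01. For epithelial-mesenchymal transition it was -0.04. What ended each call was not tested apart. Oxidative phosphorylation (adjusted p 0.0251) lost its call after median centring (0.15), spike-in centring (0.161) and the filter on dim genes (0.121), and ranged from 0.0167 to 0.0551 when 1 array was left out, above the threshold without vehicle replicate 3 (0.0538) and PD0332991 replicate 1 (0.0551). Over all its alternatives it ranged from 0.00465 to 0.418. Glycolysis was called after median centring (0.0482) and by fry (0.0247), in a range of 0.0247 to 0.410, and leukocyte markers with the mean of probe sets (0.0394), without probe sets with shared probes (0.0348) and by fry (0.0023), in a range of 0.0023 to 0.211; the cause was not tested. Apart from these, the 25 lists kept their side of the threshold under every alternative. Calls within lists moved too: with the block 4 of 16 antigen presentation, 9 of 33 lysosome, 5 of 28 unfolded protein response, 6 of 24 immediate early, 2 of 14 leukocyte and 12 of 27 p53 genes rose, 4 of 39 MYC genes fell, and 1 of 30 luminal genes rose and 3 fell. With trend and robust settings 11 antigen, 20 unfolded protein, 7 fatty acid, 5 glycolysis, 7 luminal and 4 basal genes rose and 17 MYC and 10 oxidative phosphorylation genes fell. With the filter on dim genes 19 unfolded protein and 6 fatty acid genes rose and 17 MYC and 8 oxidative phosphorylation genes fell, and with a pseudocount of 64 the last count was also 8. Of the 80 named genes that were called 44 kept their call under every alternative; of 1496 values for all 84 named genes 1337 kept their side of the threshold, 156 lost the call, 1 gained it (E2f1 with the mean of probe sets) and 2 reversed. Ndufb8 had a log2 fold change of 0.026 with the mean of its probe sets and Laptm5 of 0.047 without probe sets with shared probes, since other probe sets then enter. The call of Cdk4 was also lost with the replicate block, both forms of spike-in centring and without probe sets with shared probes, and that of Rb1 with the block and the mean of probe sets. Signal over background limits genes near the pseudocount of 16, such as Cdkn2a.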

Other observations

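The test of neighbouring genes was planned before its result was seen; the genes named in this part lie outside the named-gene rule and were chosen after their values were seen.

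Called genes outside the lists included the following, picked singly and not tested as groups. The immunity-related GTPase gene Iigp1 rose from an intensity of 60.9 ± 4.45 to 146 ± 18 (SD, n = 3 each, log2 fold change 1.07, adjusted p = 0.00111). Igtp, Irgm2 and Irgm1, of the same family of interferon-inducible GTPases, had log2 fold changes of 0.93, 0.85 and 0.82. Ifi202b, an interferon-inducible DNA-binding protein gene, had one of 0.96, on a probe set with shared probes. Also higher were the collagen gene Col8a1 (log2 fold change 1.17, SE 0.06, adjusted p = 0.000117), Thbs1, thrombospondin 1 (0.83), the cytokine gene Lif (0.78), the activin subunit gene Inhba (0.80) and the EGF-family ligand genes Hbegf (0.64) and Epgn (0.79).

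Among single genes that fell, the chromatin protein gene Hmgb2 fell from an intensity of 4492 ± 162 to 1639 ± 53.4 (SD, n = 3 each, log2 fold change -1.45), and Stmn1, which destabilizes microtubules, from 7057 ± 15.0 to 3057 ± 110 (SD, n = 3 each). H2ax, a histone variant of DNA damage signalling, had a log2 fold change of -1.47, and Skp2, a ubiquitin ligase subunit that targets the CDK inhibitor p27, had one of -0.91 on its brightest probe set, with all 6 probe sets called lower. The histone methyltransferase gene Ezh2 had a log2 fold change of -0.77 and the transcription factor genes Myb and Mybl1 had -0.88 and -0.85.

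Called genes lay next to each other on chromosomes more often than in shuffled orders. Of 18032 genes placed in the reference order, 1783 were called higher, and 221 adjacent pairs were both higher, against a median of 176 and a highest value of 218 in 10000 shuffles (one-sided permutation p = 1e-04, the smallest these shuffles can give). For the 2022 genes called lower there were 277 pairs, against a median of 226 and a highest value of 279 (one-sided permutation p = 2e-04). A run of 5 higher genes on chromosome 16 held Parp14, Dtx3l and Parp9, with log2 fold changes of 0.67, 0.31 and 0.38. A run of 4 lower genes on chromosome 1 began with Dtl and ended with Nek2, with log2 fold changes of -1.0 and -1.89. The hypothesis is that neighbours may share regulation, or that related neighbours share probe sequence. The shuffles did not hold signal level. Of the 3820 called genes, 3139 were among the 9097 of 18194 genes that passed the filter on dim genes. If genes of like signal lie together, more pairs could arise without either cause, which was not tested. These counts cannot separate the possibilities, and overlapping transcripts were not tested.

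Some genes gave called probe sets of opposite sign. Slc16a4 had log2 fold changes of -0.70 on its brighter and 0.63 on its dimmer probe set. Cadm1, a cell adhesion gene, had -0.28, -0.25 and -0.23 on 3 probe sets and 0.54 on a dimmer one. Transcript forms were not analysed here.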
